A study of Homo sapiens with 36 samples.

How the data were processed

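The values used were deposited by the authors as log2 expression levels, 1 column per array and 1 row per Ensembl gene identifier. RMA made them, per the submitters' processing notes; its version, settings, probe set definition and annotation build are not given in the sources used here. Per the labels' protocols, HepG2 cells were exposed to compound or solvent in fresh medium, RNA was taken with a column kit and a DNase step, RNA of high integrity was kept, and biotin-labelled cRNA was made with a 3' IVT kit. The table held 18981 rows, of which 18919 were genes and 62 were Affymetrix control rows, and no value was missing. Levels ran from 0.61 to 15.29, and array medians from 3.32 to 3.46. No further background correction, normalization or filter was applied for the reported values. RMA makes arrays alike in distribution, so a shift of most genes in one direction would not be seen.

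Groups came from the sample titles and labels: 3 treatments (10 mM APAP, 0.5 mM APAP, 0.5% DMSO) at 4 times, with 3 arrays each. Whether the APAP medium also held DMSO is not clear from the labels, so a solvent difference between groups is not excluded. One linear model with a mean for each of the 12 groups was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 24 residual degrees of freedom), so all comparisons shared 1 estimate of the spread. Each dose was compared with DMSO at each time and averaged over times, the 2 doses were compared with each other, and moderated F tests asked whether an effect, or the DMSO level, differed between times. Adjusted p-values are Benjamini-Hochberg values over all 18919 genes, with a threshold of 0.05. Genes of the high-dose response were tested at the low dose with camera. Comparisons, tests and most alternatives were fixed before the data were examined. The F tests within 10 mM and within 0.5 mM, the culture-time score, the checks of control rows and the alternatives that rest on them were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.

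The gene identifiers could not be paired with names. The reference table, of assembly GRCh38.p14, held 59792 rows and no Ensembl identifier, and 0 of the 18919 identifiers matched. The rule for named genes, which asked for a gene symbol, the cell type markers and the 29 gene lists fixed beforehand were therefore not run. In their place, 2 identifiers that rose and 2 that fell are given: those past the threshold at all 4 times, with no overlap between 10 mM and DMSO arrays at any time, and with the largest mean change. That rule was set after the data were seen; 1093 raised and 961 lowered genes met its first 2 conditions. For the same reason the few genes called at 0.5 mM at 12 and 24 h are not named.

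The replicate numbers come from the sample titles. Deviations from the group means were correlated between arrays of the same number within a time: 30 of 36 pairs had r over 0.1, with a range of -0.03 to 0.35. All 3 pairs were over 0.1 in 5 of the 8 comparisons with DMSO (10 mM at 24, 48 and 72 h, 0.5 mM at 48 and 72 h), and the numbers were taken to pair the arrays there.

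The fit was tested on simulated arrays with the real means and spreads, over 18919 genes of which 200 were changed. For 10 mM against DMSO at 12 h it recovered 52.5% of log2 changes of 0.5, 94.0% of 1 and 100% of 2, and 4.31% of its calls were false. For the average over times it recovered 94.0%, 99.6% and 100%, and 5.28% of its calls were false. In further simulations over 18919 genes, a culture-time score of 0.3 was recovered as 0.303. The F test over times in DMSO called 470 genes where 600 were changed, 26 of the called ones being unchanged. The signature test called 2 of 2 sets with a simulated effect and 0 of 6 without. The noise in all these simulations was independent between genes. They therefore do not show how often the signature test calls falsely where genes are correlated.

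The alternatives were a fit of each time alone, the replicate number as a block within times or over all times, median centring, a second quantile normalization, a filter on low levels, a variance prior with trend and robust estimation, array weights, a minimum of 1.5-fold change, other set tests and signature sizes, and each array left out in turn. Added alternatives left out arrays with weak spike-ins (mean of the dap control rows under log2 7) or with actin rows that differed by over log2 3 between ends, took the signature only from genes steady in DMSO, or had the difference between the 3' and 5' rows of GAPDH as a covariate, whose slope rests on differences within groups. The result of 1 human control transcript is not reported here.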

Results

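Gene expression was measured on 36 Affymetrix arrays in HepG2, a human cell line derived from a liver tumour. The cells were exposed to acetaminophen (APAP), an analgesic that damages the liver in overdose, at 10 mM or 0.5 mM, or to the solvent DMSO at 0.5%. RNA was labelled as taken after 12, 24, 48 or 72 h, which gives 12 groups of 3 arrays, described in the labels as biological replicates. The extraction text in the labels speaks of 24 h for all samples, so the times used here rest on the sample titles and the time labels alone. Each array gave a log2 level for 18919 genes. Arrays of one group correlated with r of 0.99 or more across genes, and no pair of arrays was identical (highest r 0.998). The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.12 on the log2 scale. The files pair no gene identifier with a gene name, so the changes are given as numbers of genes, and 4 genes are given by identifier.

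The first comparison asked which genes differed between the high dose and the solvent at each time. At 10 mM, 2690 genes were higher and 2338 lower than in DMSO at 12 h, 2891 and 2591 at 24 h, 3081 and 2818 at 48 h, and 3207 and 3116 at 72 h (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group). These were 26.6% of the genes at 12 h and 33.4% at 72 h. Large rises became more frequent at each step, and large falls were more frequent after 12 h without a steady increase: genes at least 4-fold higher numbered 48 at 12 h, 84 at 24 h, 230 at 48 h and 335 at 72 h, and genes at least 4-fold lower numbered 76, 117, 97 and 109. At 72 h, 56 genes were at least 16-fold higher and 6 at least 16-fold lower. The 3 treated arrays lay entirely above or below the 3 DMSO arrays for 41.1%, 40.3%, 36% and 42.7% of the genes at 12, 24, 48 and 72 h, against 10% by chance. Averaged over the 4 times, 4498 genes were higher and 4172 lower. Which direction held the majority depended on scaling: after centring each array on its median, 3976 were higher and 5074 lower in the average and 2863 and 3737 at 72 h, and after a second quantile normalization, 4276 and 4585 in the average and 2957 and 3570 at 72 h.

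**Figure D1:**
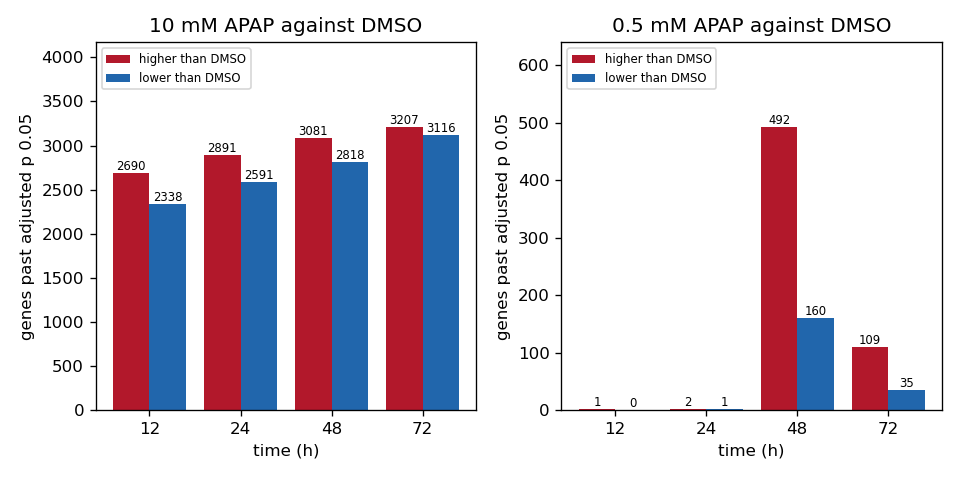
Number of genes past an adjusted p of 0.05 (vertical axes, separate scales) against time in hours, for 10 mM APAP (left) and 0.5 mM APAP (right), each compared with DMSO. Bars show genes higher (red) and lower (blue) than in DMSO; at 10 mM they number 2690 and 2338 at 12 h, and at 0.5 mM they peak at 492 and 160 at 48 h.

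Among the genes that passed the test at all 4 times, 1177 were higher and 1020 lower each time, where 11.3 and 7.86 would be shared by independent lists. The lists used the same estimated spread for each gene, so they are not independent and this is only a rough guide. The 2 largest mean rises without any overlap of arrays were those of ENSG00000102265 and ENSG00000170233, and the 2 largest measured falls those of ENSG00000196660 and ENSG00000012504. ENSG00000102265 rose by a mean log2 change of 4.09 ± 0.13 (SE; adjusted p = 1.7e-21), with 2.13 at 12 h and 5.08 at 72 h. ENSG00000170233 rose by 3.51 ± 0.08 (adjusted p = 2.9e-24), with 3.20 at 12 h and 3.23 at 72 h. ENSG00000196660 had a mean change of -5.34 ± 0.15 (adjusted p = 2.4e-22). Its level at 12 h was 3.33 ± 0.35 (SD, n = 3) at 10 mM, and 8.55 ± 0.25 in DMSO. ENSG00000012504 had a mean change of -4.67 ± 0.12 (adjusted p = 1.7e-23). From 12 to 72 h its level went from 7.35 to 9.46 in DMSO and from 3.35 to 3.80 at 10 mM. The 10 mM levels of both genes lay near the array medians of 3.32 to 3.46, and without a detection call the sizes of their falls are uncertain. At 0.5 mM and averaged over times, 2 of the 4 genes passed the test: ENSG00000170233 (0.41 ± 0.08, adjusted p = 0.0017) and ENSG00000012504 (-0.76 ± 0.12, adjusted p = 9.3e-05). At single times only ENSG00000012504 did, at 48 h (-1.22, adjusted p = 0.0018). Without DMSO 48 h replicate 1 that change was -0.86 (adjusted p = 0.045), and with only the 9 arrays of that time in the fit it did not pass (adjusted p = 0.169).

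**Figure D2:**
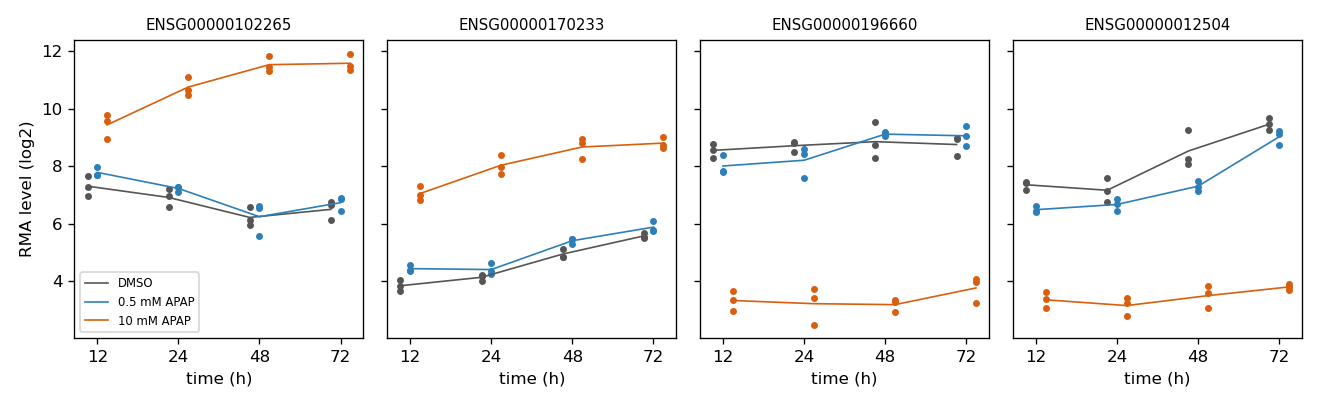
RMA level (log2, vertical axis) of the 4 genes against time in hours; points are single arrays and lines join the means of 3 arrays per group (DMSO grey, 0.5 mM APAP blue, 10 mM APAP orange). The 10 mM arrays lie apart from the DMSO arrays at every time in all 4 genes, with mean log2 changes of 4.09, 3.51, -5.34 and -4.67.

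Whether the high-dose effect itself changed with time was tested next. The difference between 10 mM and DMSO was not the same at all times in 4025 genes (limma's moderated F test). In 552 genes, all of which passed this test, the effect was called higher at one time and lower at another. Log2 changes at 12 and 72 h had a correlation of 0.45 across genes and those at 48 and 72 h one of 0.91 (genes are not independent replicates; these comparisons share no array). Of the 4025 genes, 67.2% changed more from 12 to 72 h in DMSO than at 10 mM. Their median absolute change over that interval was 0.62 in DMSO, 0.57 at 0.5 mM and 0.35 at 10 mM on the log2 scale.

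The solvent control changed with time in culture as well. Levels differed between times in 5809 genes in DMSO (30.7% of genes), in 6417 at 0.5 mM and in 4788 at 10 mM. Across genes, the change from 12 to 72 h at 0.5 mM followed that in DMSO with r of 0.94, while the change at 10 mM did so with r of 0.40. A culture-time score was formed from the 100 genes that rose and the 100 that fell most clearly from 12 to 72 h in DMSO, with 0 the mean of DMSO at 12 h and 1 that at 72 h. At 10 mM the score was 0.097 ± 0.025 at 12 h and 0.284 ± 0.011 at 72 h (SD, n = 3). At 0.5 mM it was 0.099 ± 0.019 at 24 h and 0.454 ± 0.0081 at 48 h, against 0.189 ± 0.016 and 0.719 ± 0.154 in DMSO. The 0.5 mM arrays were lower than DMSO at these 2 times by a mean of 0.178 (exact permutation stratified by time, 400 relabellings, two-sided p = 0.005, the smallest it can give). That test ignored the pairing at 48 h; with those pairs kept, the exact permutation gave p = 0.0125 with 160 relabellings, again the smallest. Without DMSO 48 h replicate 1 the mean was 0.134 (exact permutation, 200 relabellings, two-sided p = 0.005, the smallest), and without its pair and with pairs kept it was 0.137 (exact permutation, 80 relabellings, two-sided p = 0.025, the smallest). This score was devised after the data had been seen.

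**Figure D3:**
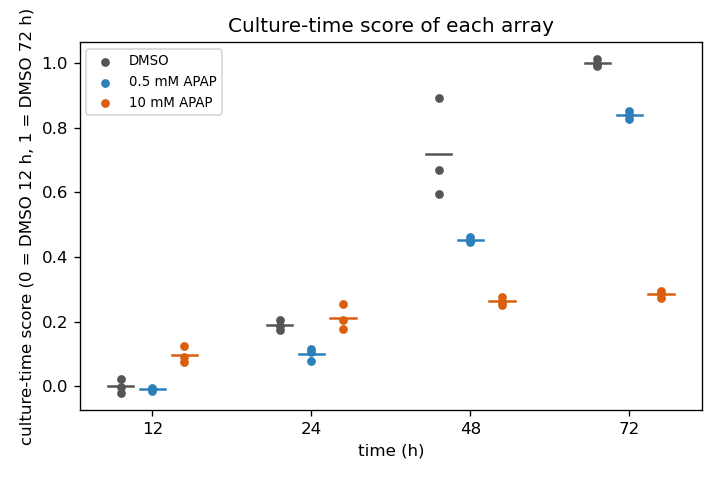
Culture-time score (vertical axis, no unit, 0 = mean of DMSO at 12 h, 1 = mean of DMSO at 72 h) of each array against time in hours; points are arrays and short lines group means. DMSO arrays at 12 and 72 h define the scale; at 72 h the 10 mM arrays average 0.284, and DMSO 48 h replicate 1 scores 0.892 against 0.669 and 0.597 for the other DMSO arrays of that time.

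At the low dose, with all 36 arrays in the fit, few genes passed the test at 12 and 24 h and more at 48 and 72 h. At 0.5 mM, 1 gene was higher than in DMSO at 12 h, and 2 genes were higher and 1 lower at 24 h, with 865 and 1168 genes at an unadjusted p under 0.05 in limma. Chance alone would place a share of 0.05 of all 18919 genes there, which the number at 12 h did not reach. At 48 h, 492 were higher and 160 lower, and at 72 h, 109 were higher and 35 lower. With the replicate number as a block these totals of 652 and 144 became 1004 and 299. Averaged over times, 784 genes were higher and 391 lower, and with the block 1048 and 709. The share of higher genes depended on scaling: after centring each array on its median, 418 were higher and 224 lower at 48 h and 643 and 535 in the average, and after a second quantile normalization, 440 and 264 at 48 h and 5 and 1 at 24 h.

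The 48 h total at the low dose rested on the spread shared by all 36 arrays and on single arrays. With only the 9 arrays of a time in the fit, 4 genes passed the test at 12 h, 30 at 24 h and 5 at 48 h, so the order of 24 and 48 h turned. The number at 72 h stayed within 1.5 times of the 144 in the full fit, so the order of 48 and 72 h turned as well. With array weights the numbers at 12, 24 and 48 h were 37, 19 and 347. The 48 h total was 201 without DMSO 48 h replicate 1, 336 without 0.5 mM APAP 48 h replicate 2 and 1034 without DMSO 48 h replicate 3. The 72 h total was 33 without DMSO 72 h replicate 1, 280 without DMSO 72 h replicate 3, 82 and 59 without 0.5 mM APAP 72 h replicates 1 and 3, and 280 without DMSO 48 h replicate 1. Without that last array, 36 genes passed the test at 24 h, and the single gene at 12 h no longer passed it without any one of the 6 arrays compared there. The actin control rows differed by 3.63 and 3.97 log2 between the 3' and 5' ends in 0.5 mM APAP 48 h replicate 2 and 72 h replicate 3, and by 1.49 to 2.45 in the other arrays. Without these 2 arrays, 360 genes passed the test at 48 h and 61 at 72 h.

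Of the 652 genes called at 48 h at the low dose, 524 (80.4%) moved in the direction that 10 mM gave at the other 3 times, and of the 144 at 72 h, 111 (77.1%) did. Over all genes the 2 log2 changes had a correlation of 0.30 at 48 h and 0.25 at 72 h. In all, 81 genes were called at both times in one direction, where independent lists would share 3.13, and 0 were called in opposite directions. The 2 lists are not independent, since each gene had the same estimated spread in both.

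Genes that differed most clearly from DMSO at the high dose also shifted from DMSO at the low dose. Whether the APAP medium also held DMSO is not clear. A solvent difference common to both doses is therefore not excluded, here or for the shared directions above. For each time, the 100 genes most clearly raised and the 100 most clearly lowered at 10 mM were taken from the other 3 times. The changes behind list and test thus shared no array. The ranking weighed each change by a spread from all 36 arrays, the tested ones included. The raised genes had median log2 changes at 0.5 mM of 0.23, 0.24, 0.24 and 0.09 at 12, 24, 48 and 72 h, with 96, 88, 84 and 71 of 100 above 0. The lowered genes had medians of -0.12, -0.17, -0.06 and -0.09, with 80, 86, 62 and 70 of 100 below 0. With the signature taken only from genes steady in DMSO over time, a choice made after the data were seen, the medians were 0.11, 0.11, 0.12 and 0.08 for the raised genes and -0.12, -0.14, -0.05 and -0.05 for the lowered genes, and the lowered genes at 48 h missed the threshold (adjusted p = 0.051). That filter also used the DMSO arrays of the tested time. The difference between the 3' and 5' rows of the GAPDH control was 0.12, 0.09, 0.21 and 0.14 log2 at 0.5 mM and 0.02, -0.01, 0.08 and 0.19 in DMSO at 12, 24, 48 and 72 h. With it as a covariate, also chosen after the data were seen, the medians were 0.25, 0.23, 0.26 and 0.09 for the raised genes and -0.12, -0.17, -0.06 and -0.10 for the lowered genes, and all 8 tests passed the threshold. All 8 tests passed the threshold with limma's camera and a preset correlation between genes of 0.01, the largest adjusted p being 0.0075 for the lowered genes at 48 h. With an estimated correlation 6 held, and the lowered genes at 48 h (adjusted p = 0.156) and the raised genes at 72 h (adjusted p = 0.0511) did not. With fry the lowered genes at 48 h had an adjusted p of 0.0952, and with camera they missed the threshold without 10 mM APAP 24 h replicate 3 (adjusted p = 0.123) or DMSO 48 h replicate 3 (adjusted p = 0.104). Their median was -0.02 without DMSO 48 h replicate 2, and that of the lowered genes at 72 h was -0.06 without DMSO 72 h replicate 1 and -0.14 without replicate 2.

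**Figure D4:**
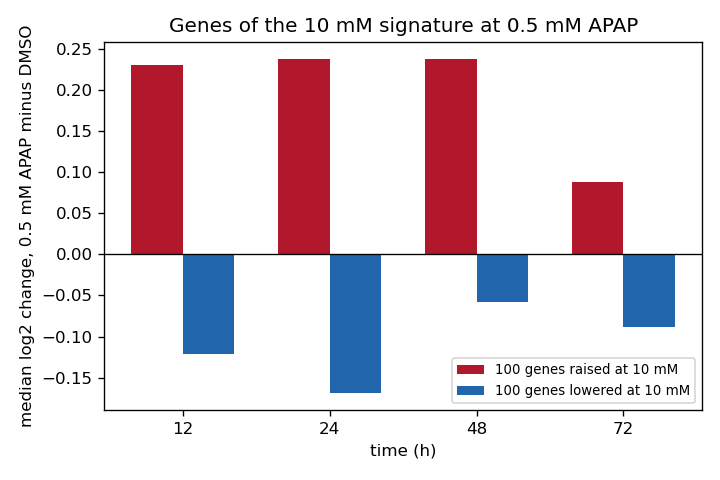
Median log2 change at 0.5 mM APAP minus DMSO (vertical axis) against time in hours, for the 100 genes raised (red) and the 100 lowered (blue) at 10 mM APAP at the other 3 times. The raised genes lie above 0 at every time (0.23 at 12 h, 0.09 at 72 h) and the lowered genes below 0 (-0.12 at 12 h, -0.09 at 72 h).

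Set against each other and averaged over times, the 2 doses differed in 8116 genes, with 4171 higher and 3945 lower at 10 mM than at 0.5 mM. The largest differences were 3.83 and -5.22 on the log2 scale. The low-dose effect differed between times in 16 genes (1165 at an unadjusted p under 0.05 in limma, where chance gives a share of 0.05 of all 18919). Leaving out single arrays moved the number of 16 by over 1.5 times for 14 of the 36, from 2 without 0.5 mM APAP 48 h replicate 1 to 137 without DMSO 48 h replicate 3.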

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

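The weighing tests in this part were chosen after the results they bear on had been seen; the relabelling of the unaltered values that ignores pairs was not.

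The effect of 10 mM APAP differed between times in 4025 genes, by a test of the difference itself. Of these genes, 2285 also differed between times within the 10 mM arrays and 3019 within the DMSO arrays. Only the DMSO test passed in 1603, only the 10 mM test in 869, and both in 1416. Neither treatment was thus the only one called to change in all of them. Over all genes, 25.3% differed within 10 mM and 30.7% within DMSO, and the 4025 were picked by a test on the same arrays. That choice can raise such shares. At an adjusted p under 0.05, however, false calls would be a small part of the 4788 and 5809 genes called among all genes. The 2285 and 3019 thus argue against a change of the DMSO arrays alone, or of the 10 mM arrays alone, as the account of all 4025. For a single gene, a test not passed does not show a lack of change. The 6 arrays with weak spike-ins do not account for the total of 4025, which was 3457 without them. A joint hypothesis stays open and was not tested. Under it the high dose may both hold back the change seen in solvent over time and add changes of its own. In 100 relabellings of 10 mM and DMSO arrays within each time, 3 gave as many genes, the real one included, with 4592 in the highest other. With the pairs by number kept where they hold, 12 of 100 did, with 8042 in the highest other. Of those 11 others, 7 had all labels exchanged at a time and real ones at another, and 4 did not, with up to 6483. Both relabellings move the dose effect itself and so make differences between times: on simulated arrays with a dose effect and no such difference, 19 relabellings with pairs kept called up to 5313 genes, and 0 once the mean dose effect was taken out. These simulated arrays had independent noise, without the correlation within pairs of the real arrays. With a simulated time difference and the mean dose effect taken out, the real labels gave 2308 genes and the highest other 2125. In the data, with each gene's mean dose effect first taken out, only the real one of 100 was as large. The highest others were 759 with pairs ignored and 3195 with pairs kept, which argues against chance but does not exclude it. All relabellings but the first were added after the results had been seen.

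In 552 of these genes the 10 mM effect was called in opposite directions at different times; 405 genes were opposite between 12 and 72 h and 8 between 48 and 72 h.

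The effect of 0.5 mM APAP differed between times in 16 genes by the same kind of test. Of 100 relabellings of 0.5 mM and DMSO arrays within times, 9 gave as many, the highest other 161, and with the pairs kept 26 of 100 did, the highest other 470. Of those 25 others, 7 had all labels exchanged at a time and real ones at another, and 18 did not, with up to 176. With each gene's mean dose effect taken out, 2 of 100 were as large with pairs ignored, the highest other 32, and 1 with pairs kept, the highest other 15. The first relabelling, the only one fixed beforehand, does not exclude chance, and the others were added later and differ, so this is left open.

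DMSO 48 h replicate 1 lies near the DMSO 72 h arrays. On a culture-time score whose change and scale came from 0.5 mM arrays, it scored 0.994 and its group mates 0.774 and 0.706. The genes of that score were ranked with a spread from all 36 arrays, so it is not wholly free of the DMSO arrays. A swap with a DMSO 72 h array would need one out of place there, and the lowest of them scored 1.08. A DMSO 72 h array under a wrong label is argued against by the gap of 0.084 below that lowest score, though the gap is only slightly above the 0.068 between its group mates. The other 5 arrays that lack spike-ins were shifted from their mates by at most 0.072 against 0.254. All but DMSO 24 h replicate 1 were 10 mM arrays, whose group means spanned only 0.085 to 0.326 on this score. A shift with culture time would thus be small in them. Whether missing spike-ins could shift such arrays further was not tested. In DMSO 24 h replicate 1 the shift was -0.018, but its dap rows averaged 5.27 log2 against 2.85. These arrays therefore do not decide whether missing spike-ins play a part. A culture that was further along, or a sample from elsewhere, may account for the place of DMSO 48 h replicate 1 and was not tested. No biological explanation was tested since the design gives none.

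The calls at 0.5 mM were most numerous at 48 h. Without DMSO 48 h replicate 1 the number at 48 h was 201, below the 280 at 72 h in the same fit, so the peak at 48 h may come from that array. A slower change with culture time at 0.5 mM is a hypothesis that remains: without that array the 0.5 mM arrays still scored lower than DMSO at 24 and 48 h (exact stratified permutation p = 0.005, and without its pair and with pairs kept 0.025, each the smallest possible). A part of that array and a slower change can hold together.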

How the results depend on the processing

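The comparisons of 10 mM with DMSO, of the 2 doses, and of times within DMSO stayed within 1.5 times of the reported number under all alternatives run except a minimum change of 1.5-fold, which by construction keeps fewer genes: 2687, 3042, 3360 and 3621 for 10 mM at 12, 24, 48 and 72 h, 2845 averaged, 2417 between doses, and for 0.5 mM 398 at 48 h and 153 averaged. The other changes were in the low-dose numbers, and apart from fewer arrays their cause was not tested. With only the arrays of the same time, 0.5 mM gave 4 genes at 12 h, 30 at 24 h and 5 at 48 h. The number at 72 h stayed within 1.5 times of the reported one, so 48 h no longer had the most calls. With the replicate block within each time it gave 0, 5, 1004 and 299 at the 4 times, and 1757 averaged, of which 709 were lower against 391 without it. The block moved no other total by over 1.5 times and changed no other call, the 8 signature tests included. For times within DMSO or another treatment this block is no check of the reported number. It lies within times, so the fit then compares the level of 1 replicate number at each time and not the group means. A second quantile normalization gave 6 at 24 h. Array weights gave 37, 19 and 347 at 12, 24 and 48 h and 51 for the difference between times. Without the arrays with weak spike-ins, chosen after seeing the data like the next setting, 24, 48 and 72 h gave 6, 189 and 249, and the difference between times 44. Without the 2 arrays with a high actin ratio, 48 and 72 h gave 360 and 61, and the difference between times 6. With the GAPDH ratio between ends as a covariate, chosen in the same way, 12 and 24 h gave 0 and 0. With single arrays left out, 0.5 mM gave 0 to 2 genes at 12 h, 0 to 36 at 24 h, 201 to 1034 at 48 h and 33 to 280 at 72 h, and 2 to 137 for the difference between times. A group left with 2 arrays took its spread from all groups. Of 376 alternatives to the signature tests, 370 kept direction and threshold, 6 missed the threshold and 0 reversed. The 4 identifiers kept direction and threshold at 10 mM in all 184 alternatives run. They were picked from the same data for the largest changes, so this outcome was all but fixed and says little about other genes. Scaling moved the median of all genes by at most 0.05 log2. The gene lists were not run because the identifiers have no names here, and the mean over several rows of a gene did not apply with 1 row per gene. The filter on low levels kept 10238 genes, those whose highest group mean lay above the median of all gene means. That cut is relative to the data and is not a detection call. Low levels may limit small changes, which was not tested.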

Other observations

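The tests of control rows, the signature from steady genes, the relabellings that keep pairs and the tests of differences between times within 10 mM and within 0.5 mM, with their relabellings, were chosen after the data had been seen. The control rows name a few human transcripts, which were fitted with limma over all 18981 rows. The 3 rows of GAPDH, a glycolytic enzyme, were lower at 10 mM by mean log2 changes of -0.10, -0.14 and -0.21 (adjusted p = 0.032, 0.0062 and 3.1e-05) at the 3' end, middle and 5' end. The difference between its 3' and 5' rows was larger at 10 mM than in DMSO by a mean of 0.11 log2 (exact permutation within times with pairs ignored, 160000 relabellings, two-sided p = 0.00249), with 0.05, 0.12, 0.26 and 0.28 against 0.02, -0.01, 0.08 and 0.19 at 12, 24, 48 and 72 h. At 0.5 mM it was 0.12, 0.09, 0.21 and 0.14, above DMSO at 3 of the 4 times and by a mean of 0.07 (exact permutation within times with pairs ignored, two-sided p = 0.0563). A version with pairs kept was not run for either dose. At 10 mM the size of the GAPDH change depended on the end measured. The 3' row of actin was higher at 72 h alone (0.40 ± 0.08, adjusted p = 0.00032), with -0.05, -0.11 and 0.15 at 12, 24 and 48 h and 0.10 averaged (adjusted p = 0.062). At 72 h its middle row changed by 0.38 (adjusted p = 0.037) and its 5' row by 0.40 (adjusted p = 0.40). None of the 6 rows of ribosomal RNA passed against DMSO at either dose, at a time or averaged (60 tests, lowest adjusted p = 0.0989), and 1 of them, a middle row, was lower at 10 mM than at 0.5 mM in the average (-0.27, adjusted p = 0.0266). The directions of the GAPDH changes and of actin at 72 h were the same after median centring and after a second quantile normalization.

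The poly-A spike-ins, bacterial transcripts added before labelling, were nearly missing from 6 of 36 arrays. In these the dap rows averaged 2.76 to 6.44 log2, against 11.34 to 13.20 in the others, while the bioB hybridisation rows ranged from 7.20 to 9.26. They were 10 mM APAP 12, 48 and 72 h replicate 1, 10 mM APAP 24 h replicate 2, and DMSO 24 and 48 h replicate 1, with none at 0.5 mM.

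Genes steady in DMSO over time (11889 at an unadjusted p of 0.05 or more) gave a signature that passed 7 of the 8 tests at the low dose with camera and the preset correlation, the exception being the lowered genes at 48 h (adjusted p = 0.051, with a range of 0.00016 to 0.156 over that test's 47 alternatives). An estimated correlation, with which the main signature also lost the raised genes at 72 h, was not run with this signature.

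Other splits of the arrays were counted for each number of genes. For 1 time, 6 arrays make 10 splits, too few for a share under 0.05. At 10 mM the real numbers were 5028, 5482, 5899 and 6323 and the highest others 0, 0, 101 and 2. At 0.5 mM they were 1, 3, 652 and 144 and the highest others 1, 6, 29 and 1; 2 splits were as large at 12 and at 24 h, and 1, the real one, elsewhere. For the averages, 100 relabellings within times were drawn, and 1, the real one, was as large in each case. The numbers were 8670 against at most 2210 for 10 mM, 1175 against 316 for 0.5 mM, and 8116 against 5699 between doses. That share is under 0.05, which argues against chance but does not exclude it. The same holds for differences between times, with 5809 against 4815 in DMSO, 4788 against 3899 at 10 mM and 6417 against 3711 at 0.5 mM. For the signature with the preset correlation between genes, 8 tests passed against at most 6 in the others. With an estimated correlation 6 of the real tests held, and no relabelling was run with it. These relabellings ignored the pairing of arrays by number. With pairs kept where they hold, only the real one of 100 was as large again: 8670 against 6921 for 10 mM, 1175 against 468 for 0.5 mM, 8116 against 4914 between doses, and 8 signature tests against 7. The signature number cannot exceed 8, and the real labels gave 7 without 10 mM APAP 24 h replicate 3. For the signature, chance is therefore not excluded. Differences between times within a treatment were not relabelled in that way. At a single time, the pairs allow 4 splits, too few for a share under 0.05: 5482, 5899 and 6323 at 10 mM at 24, 48 and 72 h against 0, 0 and 1, and 652 and 144 at 0.5 mM at 48 and 72 h against 0 and 0.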
